A study of Mus musculus with 4 samples.

How the data were processed

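Poly(A)-selected RNA from mouse hippocampus was sequenced in 4 libraries, 2 from mice given PBS and 2 from mice given sodium L-ascorbate, with 30 days of treatment per the series description. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was captured on oligo(dT) beads, and cDNA was primed with random hexamers. Per the file headers, each deposited file holds FPKM for 1 library, given to 2 decimals. Per the submitters' processing notes, HISAT2, Bowtie2, RSEM and DESeq2 were used with the GRCm38 build, with no version, role or order stated. The annotation release, the strand setting and any filter by the authors are not stated, so reads of overlapping or near-identical genes cannot be told apart. FPKM scales each gene by length and by the library total, so a very abundant transcript such as Ttr lowers the values of all other genes in its library. FPKM are not counts, and count models were not fitted.

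Files were joined by gene ID. Of 22173 genes, 2785 had empty cells in all samples and 19388 had values, of which 99.2% matched a gene ID of the RefSeq table of GRCm38.p6, leaving 154 unmatched. Gene positions come from that table. No mitochondrially encoded genes and 7 haemoglobin genes were listed. Depth is unknown. In 337 olfactory and vomeronasal receptor genes, which should be close to silent in hippocampus, the most frequent value above 0 was 0.0700 or 0.0600 FPKM in each sample.

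The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1), for 13372 genes with a mean of at least 1 FPKM, with group as the factor, 2 residual degrees of freedom and a prior of 2.33. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Log2 differences are ascorbate minus PBS on the log2(FPKM + 1) scale, so for genes of low FPKM they are smaller than the log2 of the printed fold, which is the ratio of the group mean FPKM. From the same fit, 36 of 39 gene lists with at least 5 tested members were compared with the other tested genes by camera with a preset correlation of 0.01, and Benjamini-Hochberg adjustment ran over the lists. Beside it stand camera with an estimated correlation and fry. Fry tests whether a list changes at all and does not compare it with other genes. The lists cover ascorbate transport, ascorbate-dependent dioxygenases, antioxidant, myosin, activity, synaptic, stress, clock, metabolic, immune and ageing genes, and markers of hippocampal fields, brain cell types, T cells, erythrocytes and tissues next to the hippocampus. For each list, the count of genes past the threshold was also taken with adjustment over the list alone. Differences between the samples with the same number are given beside the pooled ones, since the numbers are the only other label the samples carry.

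Tests, lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. Named genes are Myh9, Slc23a1 and Slc23a2, the 10 genes with the smallest unadjusted p in each direction among those whose groups did not overlap (as none passed the threshold), 2 to 4 members with the smallest p of each list discussed, Cd8a, Cd8b1 and Cd3e, and the most abundant members of lists of other tissues. The genes reported number 93, of which 89 were tested. A few further genes that the rule takes, and a test that rests on such a gene, are not reported here. Genes that share near-identical sequence or overlap them, Gm46900 among them, are named only for that reason, and Eif2s3y as a check of the samples. Transcripts of the named genes were compared with all GENCODE M21 transcripts with BLAST+ 2.17.0. Of 92 genes found there, 29 had a transcript of another gene at 95% identity or more over at least 200 bases, and 9 had one of a gene in the files over the larger part of the shorter transcript. Of the 93 genes, 15 overlap another gene of the files.

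On simulated data with the spread of the real comparison (2 against 2 samples, 13372 genes, 200 of them changed), the test recovered 4% of genes changed 2-fold, 66% of those changed 4-fold, 84% of those changed 8-fold and 96% of those changed 16-fold, with 7 false calls. Changed genes were drawn from those with a mean log2(FPKM + 1) of at least 2. The simulated samples varied independently, without the difference between the numbers that the real samples show. These shares therefore do not carry over to the real comparison, where 58 genes had a log2 difference of -2 or lower and 0 passed. The list test called the 1 shifted list and 0 of the others. Its genes were simulated independently of each other, so this cannot show how the list test behaves when genes vary together. Alternatives were pseudocounts of 0.1 and 0.5, no filter and a minimum of 5 FPKM, TPM, median-of-ratios and quantile scaling, limma without trend and with robust variances, haemoglobin genes left out with the rest rescaled to the same total, the replicate number as a block, and each sample left out in turn. With a sample left out, its group has 1 sample, which is assumed to vary like the other group. The thalamus marker mean as a covariate and the comparison without choroid plexus and meningeal markers were added after the data had been seen. Other splits of the samples were not used as a test of chance, since 2 against 2 samples allow too few.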

Results

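Gene expression was measured by RNA sequencing of polyadenylated RNA from the hippocampus of C57BL/6 mice, a common inbred laboratory strain. Of the 4 samples, 2 came from mice given phosphate-buffered saline (PBS) and 2 from mice given sodium L-ascorbate, a salt of vitamin C, and the series describes 30 days of treatment. The title of the series links ascorbic acid to the Myh9 protein, to CD8 T cells and to cognition in middle-aged mice, so the comparison asks which hippocampal transcripts differ with ascorbate. Values were deposited as FPKM, sequenced fragments scaled by transcript length and by the mapped total of the library, for 22173 genes, of which 19388 had values and 13372 had a mean of at least 1 FPKM and were tested. The FPKM summed to 391142 in PBS sample 1, 372683 in PBS sample 2, 386956 in ascorbate sample 1 and 348133 in ascorbate sample 2. Read totals are unknown, so no counting error can be given for a single value. The Y-linked gene Eif2s3y was present in every sample, at 3.04 and 2.45 FPKM with PBS and 2.89 and 2.65 FPKM with ascorbate. The labels do not say whether the samples of a group come from separate animals, so each p-value measures only the spread between these samples.

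Transcripts of the choroid plexus, the epithelium in the brain ventricles that secretes cerebrospinal fluid, were abundant in both PBS samples and scarce in both ascorbate samples. Transthyretin (Ttr, gene ID 22139, chromosome 18, 20664209 to 20674326, GRCm38), the thyroid hormone carrier secreted by this epithelium, was 7704 ± 633 FPKM (SD, n = 2) with PBS and 44.6 ± 61.6 FPKM (SD, n = 2) with ascorbate, a 173-fold difference that was 87.4-fold without ascorbate sample 2 and 7480-fold without ascorbate sample 1. It made up 2.08% and 1.95% of all FPKM in the PBS samples and 0.0228% and 2.96e-04% in ascorbate samples 1 and 2. Autotaxin (Enpp2, chromosome 15, 54838901 to 54952789) was 1274 ± 87.7 FPKM against 76.4 ± 51.7 FPKM (SD, n = 2 each), and klotho (Kl) was 56.3 ± 17.5 FPKM against 3.21 ± 1.36 FPKM (SD, n = 2 each). All 22 members of the choroid plexus list were lower in both ascorbate samples than in both PBS samples. As a set the list fell, with a median log2 difference of -3.52 (camera with a preset correlation, adjusted p = 3.03e-69), but adjusted p = 0.589 with an estimated correlation. The median was -3.19 between the samples numbered 1 and -3.83 between the samples numbered 2. Adjusted over the list alone, 21 of the 22 genes were past the threshold in limma-trend, against 0 over all genes tested. Of the 22 genes, 4 were at 1 FPKM or more in every sample, and 1, Kl, also belongs to the senescence list.

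No single gene passed the adjusted threshold of 0.05 in limma-trend, where 377 of 13372 genes had an unadjusted p under 0.05, 364 of them lower and 13 higher with ascorbate. Chance gives 668.6 for samples that vary independently. Here same-numbered samples deviated together (correlation 0.770), and each group holds 1 sample of each number. Differences between the numbers thus add to the spread within groups, so a count below 668.6 does not show a lack of differences. The smallest adjusted p, 0.0899, was shared by 6 genes of ion and water transport or membrane proteins of the choroid plexus list. Kcnj13 (gene ID 100040591, chromosome 1, 87384577 to 87394729), a potassium channel, was 34.5 ± 2.70 FPKM with PBS and 0.385 ± 0.304 FPKM with ascorbate (SD, n = 2 each), a log2 difference of -4.69 (SE 0.21). The water channel Aqp1 had a log2 difference of -3.42, the bicarbonate transporter Slc4a5 -3.56, the potassium channel subunit Kcne2 -4.76, the cation channel Trpv4 -2.90 and the membrane protein Tmem72 -3.31. Mfrp (-3.52), Wfdc2 (-3.23), Mgp (-2.31) and Steap1 (-3.43) completed the 10 lower genes with the smallest p, each at an adjusted p of 0.116. Kcnj13 lies within the span of Gigyf2, Mfrp shares transcript sequence with C1qtnf5 and Steap1 overlaps Gm46900, so the values of these 3 genes are uncertain. That of Tmem72 is uncertain as well, because transcripts of other genes are near-identical to it, such as Gm47486 (98.6% identity over 3552 bases). Both ascorbate samples lay below both PBS samples for 1924 genes (14.4%) and above them for 1157 (8.65%). Chance gives 16.7% in each direction, again only for samples that vary independently. A log2 difference of -2 or lower was measured for 58 genes, of which 27 belong to the choroid plexus or meningeal lists and 30 to no list, and one of 2 or higher for 2 genes. The lists hold only chosen markers, so belonging to no list does not place a gene outside these tissues. The unadjusted count was 182 without PBS sample 1 and 616 without ascorbate sample 1. With the mean of thalamus markers as a covariate, a choice made after the data had been seen, 367 genes passed, 358 of them lower. With the replicate number as a block, an alternative fixed beforehand, all of these 367 genes and further ones passed. That fit leaves 1 residual degree of freedom, and the labels give the number no meaning. One gene, Kcnj13, passed after quantile normalization.

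**Figure D1:**
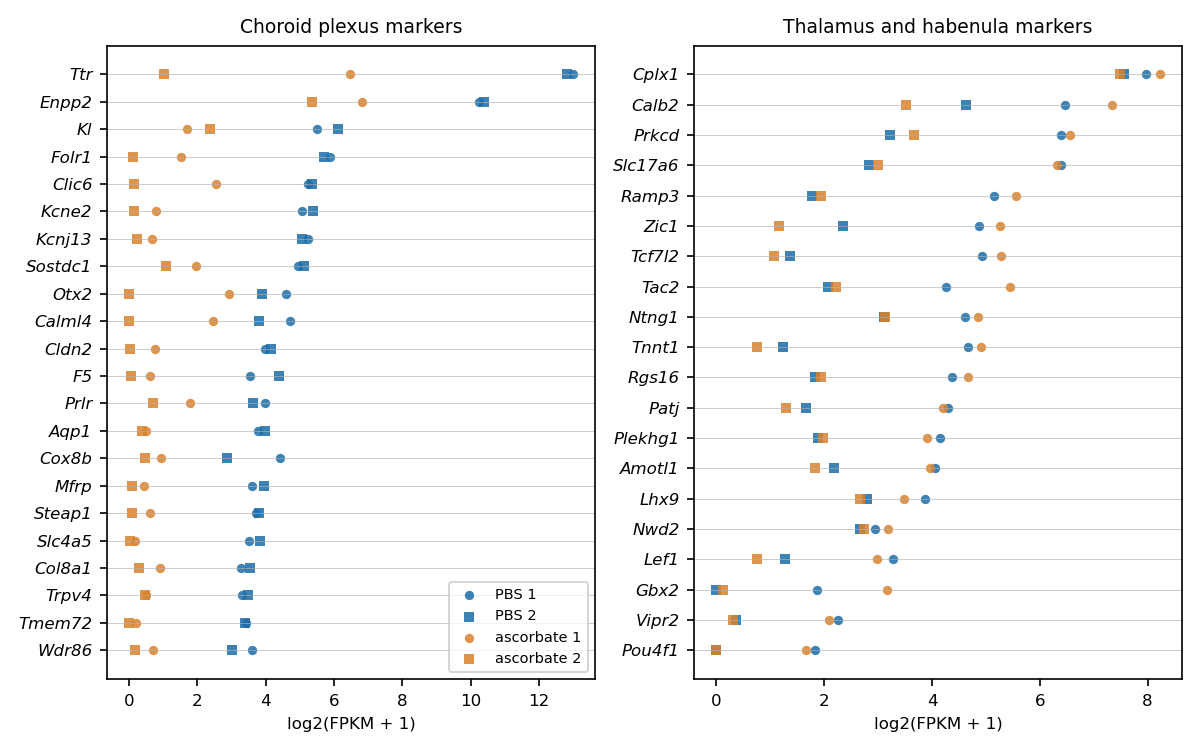
Expression of the 22 choroid plexus markers (left) and the 20 thalamus and habenula markers (right) as log2(FPKM + 1), with 1 point per sample, PBS in blue, ascorbate in orange, number 1 as circles and number 2 as squares. All 22 choroid plexus markers sit lower in both ascorbate samples than in both PBS samples, while the 20 thalamus and habenula markers sit higher in both samples numbered 1.

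Genes listed as markers of the meninges, the membranes that cover the brain, were lower in the ascorbate samples as well. Choroid plexus markers were lower in the same samples, and no test separated these tissues. Prostaglandin D synthase (Ptgds) was 1284 ± 226 FPKM with PBS and 319 ± 194 FPKM with ascorbate (SD, n = 2 each). The binding protein Igfbp2 was 108 ± 20.7 FPKM against 15.5 ± 7.54 FPKM, and the growth factor Igf2 was 81.3 ± 5.66 FPKM against 6.30 ± 4.33 FPKM (SD, n = 2 each), a 12.9-fold difference (8.68-fold without ascorbate sample 2, 25.1-fold without ascorbate sample 1). The matrix proteins Islr and Bgn had log2 differences of -1.43 and -1.60, each with an adjusted p of 0.163. All 18 tested members of the meningeal fibroblast list were lower with ascorbate, and for 16 the groups did not overlap. This held for 14.4% of all tested genes, where chance gives 16.7% in this direction for samples that vary independently. The median log2 difference was -1.56 (camera, adjusted p = 7.21e-35), but adjusted p = 0.589 with an estimated correlation. It was -1.40 between the samples numbered 1 and -1.70 between those numbered 2. Adjusted over the list alone, 14 of the 18 genes passed, against 0 over all genes tested. Of these 18 genes, 13 were at 1 FPKM or more in every sample. None of them is in another list, which does not show that they are expressed in the meninges alone.

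Markers of blood vessels, interferon-stimulated genes and genes of antigen presentation were lower in the ascorbate samples, in which the choroid plexus median differed by -3.52 from the PBS samples. No test separated these genes from transcripts of the choroid plexus and meninges, so a change within hippocampal cells is not shown. Of the vascular genes, vitronectin (Vtn), made by pericytes, was 46.1 ± 3.01 FPKM with PBS and 20.4 ± 1.27 FPKM with ascorbate (SD, n = 2 each). The thyroxine transporter Slco1c1 was 35.7 ± 4.57 FPKM against 11.2 ± 2.60 FPKM (SD, n = 2 each), and Tagln, a smooth muscle protein whose gene overlaps Pcsk7, had a log2 difference of -1.72. The endothelial and mural list fell by a median log2 of -0.37, with 18 of 19 members lower (camera, adjusted p = 2.35e-12), but adjusted p = 0.601 with an estimated correlation. The number-wise medians were -0.35 and -0.45, and 4 genes passed when adjusted over the list alone, against 0 over all genes tested.

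Among interferon-stimulated genes, the membrane tether Bst2 was 9.67 ± 1.03 FPKM with PBS and 1.67 ± 0.297 FPKM with ascorbate (SD, n = 2 each). Ifi27 had a log2 difference of -1.21 and Ifi27l2a of -1.52, and both values are uncertain because the genes overlap each other. The interferon list fell by a median log2 of -0.45, with 20 of 21 members lower (camera, adjusted p = 9.13e-12), but adjusted p = 0.887 with an estimated correlation. Its medians were -0.44 and -0.56 within numbers 1 and 2, and 4 genes passed when adjusted over the list alone, against 0 over all genes tested. The class II chain H2-Aa, which presents peptides to CD4 T cells, was 6.03 ± 0.537 FPKM with PBS and 0.395 ± 0.332 FPKM with ascorbate (SD, n = 2 each), a 15.3-fold difference with an adjusted p of 0.168 in limma-trend. The fold was 9.57 without ascorbate sample 2 and 37.7 without ascorbate sample 1. H2-Q4 had a log2 difference of -0.90, and H2-DMb1 one of -0.94, uncertain because H2-DMb2 has near-identical transcripts. The list of class I and II antigen presentation fell by a median log2 of -0.54, with 18 of 20 members lower (camera, adjusted p = 3.07e-11), but adjusted p = 0.887 with an estimated correlation. Its medians were -0.31 and -0.76 within numbers 1 and 2, and 3 genes passed when adjusted over the list alone, against 0 over all genes tested. Without ascorbate sample 2, the mean log2 difference went from -0.61 to -0.39 for the interferon list and from -0.66 to -0.41 for antigen presentation, with both lists still past the threshold (camera, adjusted p = 2.23e-05 and 2.83e-05).

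**Figure D2:**
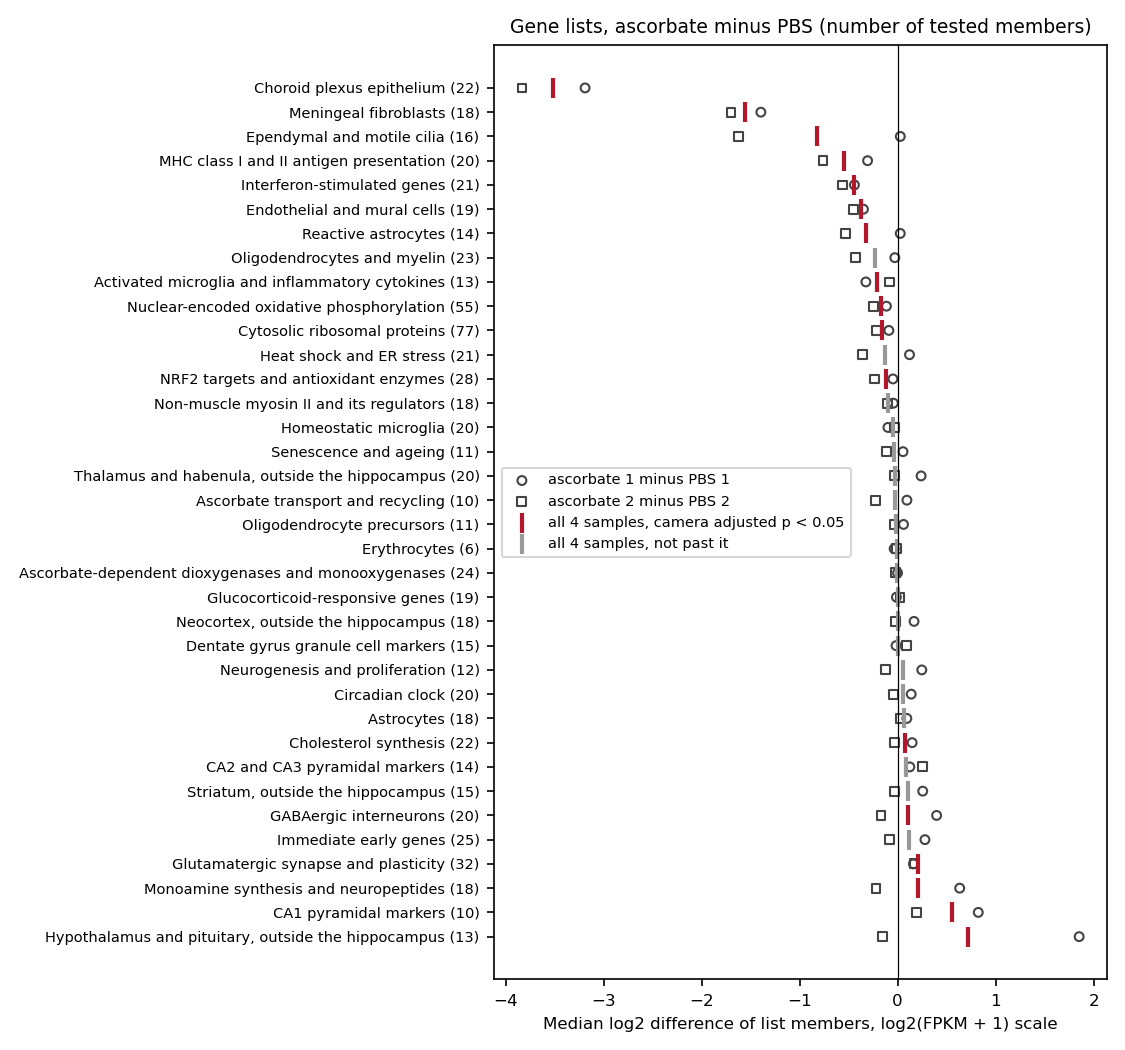
Median log2 difference, ascorbate minus PBS, of the tested members of each of 36 gene lists, with the number of members in parentheses. Vertical bars use all 4 samples, in red where camera with the preset correlation passed the threshold, and open symbols give the difference between the samples of each number, as for choroid plexus (-3.19 and -3.83) and for hypothalamus and pituitary (1.85 and -0.15).

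Of 36 lists tested, 17 passed camera with the preset correlation, 11 lower and 6 higher with ascorbate. After rescaling to TPM the split was 11 lower and 2 higher. With an estimated correlation 0 of the 36 passed, where adjusted p ran from 0.589 to 1.0. In fry 0 passed, with a smallest adjusted p of 0.167 for change in one direction and 0.0569 for change in either direction. The smallest 2-sided p that an exact permutation of 2 against 2 samples allows is 0.333.

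Beyond the 5 lists above, 6 more fell, and for each of these the call was lost without at least 1 sample. Cytosolic ribosomal protein genes were lower in all 77 members by a median log2 of -0.16 (camera, adjusted p = 8.06e-04), but adjusted p = 0.894 with an estimated correlation, with medians of -0.090 and -0.22 within numbers 1 and 2. Examples are Rpl38 (-0.35) and Rps29 (-0.31), which were -0.17 and -0.15 without PBS sample 1 and -0.14 each without ascorbate sample 2, and the mean of the list was -0.043 without PBS sample 1 (adjusted p = 0.635) and 0.023 without ascorbate sample 2 (adjusted p = 0.745). Nuclear genes of oxidative phosphorylation were lower in 50 of 55 members by a median of -0.17 (camera, adjusted p = 0.00386), but adjusted p = 0.894 with an estimated correlation, with medians of -0.11 and -0.25 within the numbers. Ndufa1 (-0.47, overlapping Rnf113a1), Atp5e (-0.28) and Ndufa6 (-0.35) had the smallest p, with values of -0.22, -0.12 and -0.091 without ascorbate sample 2, and the mean of the list was -0.024 without PBS sample 1 (adjusted p = 0.934) and 0.068 without ascorbate sample 2 (adjusted p = 0.252). Antioxidant genes and targets of the factor NRF2 were lower in 24 of 28 members by a median of -0.12 (camera, adjusted p = 0.0105), but adjusted p = 0.894 with an estimated correlation, with medians of -0.048 and -0.24 within the numbers. Extracellular superoxide dismutase (Sod3) was 11.6 and 12.5 FPKM with PBS and 3.14 and 3.28 FPKM with ascorbate, a log2 difference of -1.63 (SE 0.14). It was the 1 gene that passed when adjusted over the list alone. Choroid plexus and meningeal markers were lower in the same samples, and which cells the Sod3 difference comes from was not tested. The quinone reductase Nqo1 (-0.92) and the glutathione transferase Gsta4 (-0.41, or -0.20 without PBS sample 1) came next, and the mean of the list was -0.047 without PBS sample 1 (adjusted p = 0.635) and 0.065 without ascorbate sample 2 (adjusted p = 0.554).

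Reactive astrocyte genes were lower in 11 of 14 members by a median log2 of -0.32 (camera, adjusted p = 0.00133), but adjusted p = 0.887 with an estimated correlation, and medians were 0.027 and -0.53 within numbers 1 and 2. The members with the smallest p were the copper protein ceruloplasmin (Cp, -0.97, overlapping Hps3), the complement inhibitor Serping1 (-1.30) and Emp1 (-0.47, or -0.29 without ascorbate sample 2), and the mean of the list was -0.14 without ascorbate sample 2 (adjusted p = 0.177). Ependymal and motile cilia genes were lower in 15 of 16 members by a median of -0.83 (camera, adjusted p = 0.00195), but adjusted p = 0.887 with an estimated correlation, and medians were 0.027 and -1.63 within the numbers. The members with the smallest p were Mia (-1.57) and Pltp (-1.41, overlapping Ctsa), secreted proteins that are not parts of cilia, and Cfap65 (-0.88). In this order the 3 values were -0.79, -0.39 and -0.19 without ascorbate sample 2 and -2.35, -2.43 and -1.57 without ascorbate sample 1. The cilia gene Ccdc153 was 12.6 and 4.88 FPKM with PBS and 18.9 and 0.0900 FPKM with ascorbate, Rsph1 was 12.2 and 6.97 against 10.5 and 1.02 FPKM, and the mean of the list was 0.23 without ascorbate sample 2 (adjusted p = 0.144). Rsph1 overlaps Ubash3a. Activated microglia and cytokine genes were lower in 13 of 13 members by a median of -0.21 (camera, adjusted p = 0.0148), but adjusted p = 0.887 with an estimated correlation, and medians were -0.32 and -0.084 within the numbers. Lgals3 (-0.79), Cd9 (-0.83) and Spp1 (-1.21) had the smallest p, with values of -0.42, -0.31 and -0.36 without ascorbate sample 2 and -1.16, -1.35 and -2.07 without ascorbate sample 1. Spp1 was also -0.65 without PBS sample 1. The list did not pass without PBS sample 2 (adjusted p = 0.0881) or without ascorbate sample 1 (adjusted p = 0.259). In the 5 lists other than the antioxidant one, 0 genes passed in limma-trend when adjusted over the list alone, and 0 passed over all genes tested.

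Of the 6 lists that rose, the one of the glutamatergic synapse had 28 of 32 members higher by a median log2 of 0.21 (camera, adjusted p = 0.00128), but adjusted p = 0.887 with an estimated correlation, with medians of 0.16 and 0.17 within numbers 1 and 2. The synaptic vesicle protein Syp was 387 ± 40.0 FPKM with PBS and 492 ± 80.3 FPKM with ascorbate (SD, n = 2 each), and Vamp2 (0.32) and the postsynaptic scaffold Dlg4 (0.38) followed. The log2 difference of Syp was 0.17 without ascorbate sample 1, and those of Vamp2 and Dlg4 were 0.11 and 0.10 without PBS sample 1. The mean of this list turned to -0.075 without PBS sample 1 (adjusted p = 0.498) and to -0.080 without ascorbate sample 2 (adjusted p = 0.473). Markers of CA1 pyramidal neurons were higher in 9 of 10 members by a median of 0.55 (camera, adjusted p = 0.0148), but adjusted p = 0.887 with an estimated correlation, with medians of 0.82 and 0.19 within the numbers. Wfs1 (0.59), Lefty1 (0.66, with near-identical Lefty2) and Pou3f1 (0.53) had the smallest p, with values of 0.13, -0.0051 and -0.073 without PBS sample 1. Without PBS sample 1 the mean of the CA1 list was -0.43 and passed in the opposite direction (adjusted p = 0.0300), and without ascorbate sample 2 it was -0.13 (adjusted p = 0.745). Cholesterol synthesis genes were higher in 15 of 22 members by a median of 0.077 (camera, adjusted p = 0.0148), but adjusted p = 0.887 with an estimated correlation, with medians of 0.15 and -0.029 within the numbers. The synthase Hmgcs1 was 61.4 ± 0.431 FPKM against 73.7 ± 1.25 FPKM (SD, n = 2 each), the regulator Srebf2 had a log2 difference of 0.28 (0.16 without PBS sample 1) and the reductase Dhcr7 one of 0.24. The mean of the list was 0.029 without PBS sample 2 (adjusted p = 0.217) and -0.042 without ascorbate sample 1 (adjusted p = 0.703).

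The other 3 lists that rose had a positive median within number 1 and a negative one within number 2, as did cholesterol synthesis. Of the 22 monoamine and neuropeptide genes fixed, 11 are also in another list, as are 6 of the 20 GABAergic genes. These lists are thus not fully separate results. Of the 13 hypothalamus and pituitary genes tested, 2 were at 1 FPKM or more in every sample. Hypothalamus and pituitary genes were higher in 12 of 13 members by a median log2 of 0.72 (camera, adjusted p = 0.0113), but adjusted p = 0.887 with an estimated correlation, with medians of 1.85 and -0.15 within numbers 1 and 2. The highest values of 4 of these genes were in ascorbate sample 1, where prolactin (Prl) was 23.3 FPKM, hypocretin (Hcrt) 42.2 FPKM and Pmch 251 FPKM, and where growth hormone (Gh), listed at 0 in the other 3 samples, was 5.18 FPKM. In ascorbate sample 2, Prl was listed at 0, Hcrt was 0.220 FPKM and Pmch 0.320 FPKM, while Hap1 was 97.2 FPKM in sample 1 and 52.1 FPKM in sample 2. In PBS samples 1 and 2, Pmch was 66.4 and 0.820 FPKM and Hcrt 3.04 and 0.110 FPKM, so both were higher in the 2 samples numbered 1 than in those numbered 2. Without ascorbate sample 1 the mean of the list was -0.998 and passed in the opposite direction (adjusted p = 0.0463), and without PBS sample 2 it was -0.012 (adjusted p = 0.494). Pmch overlaps Parpbp. Genes of monoamine synthesis and neuropeptides were higher in 16 of 18 members by a median of 0.21 (camera, adjusted p = 0.0224), but adjusted p = 0.887 with an estimated correlation, with medians of 0.63 and -0.22 within the numbers. Tyrosine hydroxylase (Th) was 13.7 FPKM and the dopamine transporter Slc6a3 14.3 FPKM in ascorbate sample 1. They were 0.0700 and 0.0400 FPKM in ascorbate sample 2. With PBS, Th was 1.4 FPKM in sample 1 and 0.27 FPKM in sample 2. Slc6a3 was 1.77 FPKM in PBS sample 1 and lower in PBS sample 2. Both genes were thus higher in the samples numbered 1 than in those numbered 2, as were Pmch and Hcrt. Vgf had a log2 difference of 0.52 that was 0.11 without ascorbate sample 1 and 0.93 without ascorbate sample 2. The mean of this list was 0.55 without PBS sample 1 (adjusted p = 0.0722) and -0.42 without ascorbate sample 1 (adjusted p = 0.458). GABAergic interneuron genes were higher in 14 of 20 members by a median of 0.11 (camera, adjusted p = 0.0432), but adjusted p = 0.887 with an estimated correlation, with medians of 0.40 and -0.17 within the numbers. The transcription factors Dlx1 (0.52), Dlx5 (0.44) and Dlx2 (0.33) had the smallest p, with values of 0.20, 0.15 and 0.20 without PBS sample 1, and the mean of the list was -0.0049 without PBS sample 1 (adjusted p = 0.984) and -0.069 without ascorbate sample 1 (adjusted p = 0.573). In the 6 lists that rose, 0 genes passed in limma-trend either over the list alone or over all genes tested. TPM ended the calls of the hypothalamus, CA1, monoamine and GABAergic lists.

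The 10 genes with the smallest p among those higher with ascorbate, none of them past the threshold, had unadjusted p in limma-trend from 2.78e-04 to 0.0404. The predicted gene Gm15501 (gene ID 100040298, chromosome 7, 93178962 to 93184176) was listed at 0 in both PBS samples and at 5.71 and 9.66 FPKM in the ascorbate samples, with an adjusted p of 0.160, and is uncertain because transcripts of other genes are near-identical to it. The T cell kinase Zap70 was 2.01 ± 0.134 FPKM with PBS and 3.64 ± 0.00707 FPKM with ascorbate (SD, n = 2 each). Its log2 difference was 0.63 (SE 0.16), with an adjusted p of 0.9998 in limma-trend. The T cell gene Cd3e was at most 0.150 FPKM, so Zap70 alone does not show T cells. Rasd1, a Ras-related gene induced by glucocorticoids, was 11.6 ± 0.672 FPKM against 21.3 ± 5.78 FPKM, and the neuropeptide gene Nts was 5.41 ± 0.361 FPKM against 8.65 ± 1.88 FPKM (SD, n = 2 each), with log2 differences of 0.79 and 0.58, or 0.52 and 0.38 without ascorbate sample 1. The receptor Gpr83 had a log2 difference of 0.65 and the ion transport regulator Fxyd7 one of 0.52, which were 0.40 and 0.34 without PBS sample 1. Xlr3a (0.84), Xlr4b (0.65), Gm9234 (1.11) and the proteoglycan gene Gpc1 (0.41) are uncertain, because Xlr3b, Xlr4a, Ppia and Ankmy1, in that order, carry near-identical transcripts. Rasd1 overlaps Med9.

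Myh9, the non-muscle myosin heavy chain named in the title, differed by less than the spread between samples. Myh9 (gene ID 17886, chromosome 15, 77760585 to 77842175) was 15.0 ± 3.51 FPKM with PBS and 15.7 ± 4.62 FPKM with ascorbate (SD, n = 2 each). Its log2 difference of 0.046 had a 95% confidence interval from -0.71 to 0.80 in limma-trend (adjusted p = 1.0). It was -0.18 without PBS sample 1 and -0.24 without ascorbate sample 2. The list of non-muscle myosin II and its regulators had a median log2 of -0.10 (camera, adjusted p = 0.262), where the light chain Myl9 had a log2 difference of -0.94 and Myl12a, which has a near-identical copy in Myl12b, one of -0.59 (-0.31 without ascorbate sample 2). The ascorbate transporter Slc23a2 (gene ID 54338, chromosome 2, 132052496 to 132145320) was 35.4 ± 1.99 FPKM with PBS and 27.0 ± 1.70 FPKM with ascorbate (SD, n = 2 each). The log2 difference was -0.38 (limma-trend, unadjusted p = 0.0516), with an adjusted p of 1.0. Both ascorbate samples were below both PBS samples, as for 14.4% of all tested genes. Which cells this difference comes from was not tested. Slc23a1, another ascorbate transporter, was 0.810 ± 0.0849 FPKM against 0.825 ± 0.219 FPKM (SD, n = 2 each), below the level for testing, and overlaps Paip2. The list of ascorbate transport and recycling had a median log2 of -0.022 (camera, adjusted p = 0.422), with Cyb561, an ascorbate-dependent reductase, at -0.61. That of ascorbate-dependent dioxygenases had a median of -0.011 (camera, adjusted p = 0.724), with Tmlhe at -0.28 (-0.15 without PBS sample 1) and the histone demethylase Kdm4b at 0.31 (0.056 without ascorbate sample 2).

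Most T cell transcripts were below 1 FPKM in mean. Cd8a was 0.420 and 0.180 FPKM with PBS and 0.330 and 0.370 FPKM with ascorbate, Cd8b1 was 0.0800 FPKM in 1 sample of each group and listed at 0 in the others, and Cd3e was at most 0.150 FPKM. Of 34 T cell genes, 31 had values and 1, Zap70, reached the mean of 1 FPKM needed for testing, so the list itself was not tested. The highest mean among the others was 0.808 FPKM, and no test was made of them.

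**Figure D3:**
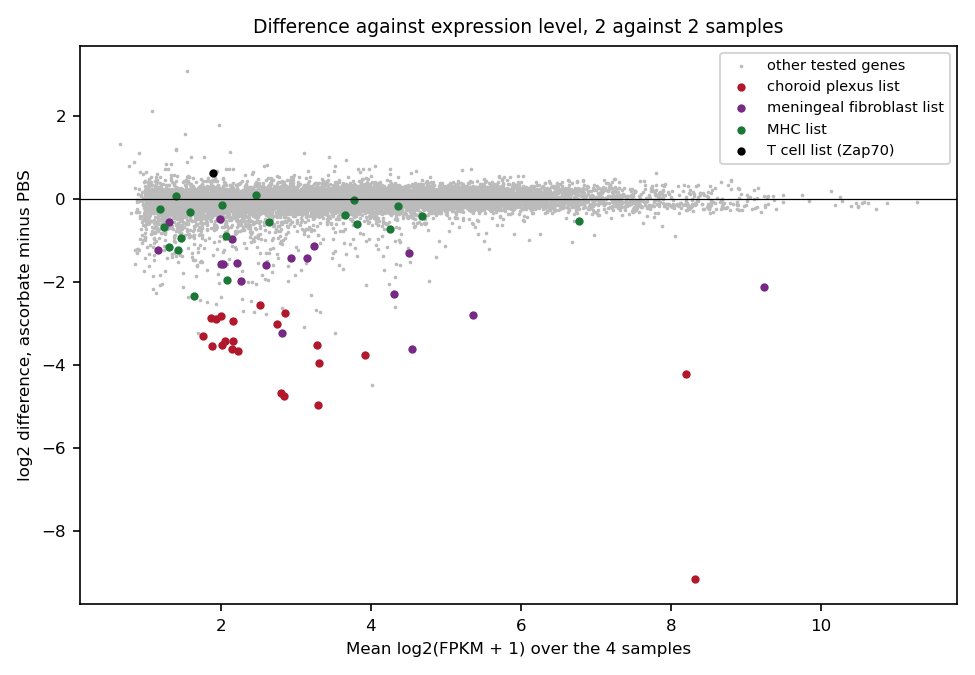
Log2 difference, ascorbate minus PBS, of each of 13372 tested genes (vertical axis) against its mean log2(FPKM + 1) over the 4 samples (horizontal axis), with the choroid plexus, meningeal fibroblast and MHC lists and Zap70 in colour. The choroid plexus genes lie between -2.57 and -9.16, with Ttr the lowest, while the median of all genes is -0.018.

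Lists of several brain cell types, neighbouring tissues and regulatory programmes did not pass the list test. Immediate early genes had a median log2 of 0.11 (camera, adjusted p = 0.134) and neocortex markers one of 0.0060 (adjusted p = 0.168). The adjusted p was 0.262 for astrocytes (median 0.062), striatum (0.11) and circadian clock genes (0.056). Oligodendrocyte and myelin genes had a median of -0.23 (adjusted p = 0.347), heat shock and ER stress genes one of -0.13 (adjusted p = 0.422), and CA2 and CA3 markers one of 0.088 (adjusted p = 0.430). Dentate gyrus markers had a median of 0.0060 (adjusted p = 0.503) and homeostatic microglia one of -0.047 (adjusted p = 0.530). Neurogenesis genes had a median of 0.054 and a mean of -0.0035 (adjusted p = 0.632), and CA2 and CA3 markers a mean of -0.0024, both tested upward. Oligodendrocyte precursors had a median of -0.014 (adjusted p = 0.445) and thalamus and habenula markers one of -0.024 (adjusted p = 0.452), although their means, 0.033 and 0.031, and tests pointed upward. The dioxygenase and glucocorticoid lists had negative medians and means and a test that pointed upward. Glucocorticoid-responsive genes had an adjusted p of 0.995 and erythrocyte genes one of 1.0. The senescence list had a median of -0.035 (adjusted p = 0.724), with Cdkn1a at a log2 difference of 0.41, and Kl passed when adjusted over this list alone. Of the sex-linked genes 1 was tested, and 0 mitochondrially encoded genes were listed, so neither list was tested.

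Samples with the same number were closer to each other than samples of the same group. Across tested genes, Pearson's r of log2(FPKM + 1) was 0.976 between PBS 1 and ascorbate 1 and 0.972 between PBS 2 and ascorbate 2. It was 0.961 between the PBS samples and 0.943 between the ascorbate samples, and 0.925 and 0.950 for PBS 1 with ascorbate 2 and PBS 2 with ascorbate 1. These correlations run across genes, which are not independent replicates, and carry no p. Between 0.172% and 0.269% of tested genes had identical values in a pair of samples. The thalamus marker Prkcd was 83.1 and 8.30 FPKM in PBS samples 1 and 2 and 92.8 and 11.8 FPKM in ascorbate samples 1 and 2. Calb2 was 87.8 and 23.9 against 161 and 10.5 FPKM, and Cplx1 was 250 and 188 against 298 and 178 FPKM. Among myelin genes, Mbp was 2075 and 1166 against 2048 and 1006 FPKM and Trf was 272 and 128 against 264 and 75.5 FPKM. The median difference of thalamus markers, ascorbate minus PBS, was 0.24 within number 1 and -0.029 within number 2.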

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

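The thalamus covariate and the comparison without choroid plexus and meningeal markers were chosen after the data had been seen. Leaving out the choroid plexus and meningeal markers does not remove other transcripts of these tissues. That comparison therefore cannot separate the other results from them. The count of 0 genes held with both pseudocounts, both filters, TPM, median of ratios, both limma variants, haemoglobin genes left out with the rest rescaled, choroid plexus and meningeal markers left out, and each sample left out (0 to 0, with 182 to 616 genes at an unadjusted p under 0.05). Quantile normalization gave 1 gene, the replicate block 485 (453 lower, 32 higher) on 1 residual degree of freedom, and the thalamus covariate 367. On data simulated with the spread of the blocked fit (13372 genes), 100% of genes changed 2-fold, 4-fold, 8-fold or 16-fold were recovered, with 17 false calls and 1 unshifted list called. Those data held no difference between the numbers and were tested with group alone. They therefore say nothing about the block fit or its calls. The samples share only a number. Deviations from group means correlated at 0.770 between same-numbered samples, and a first principal component with 66.4% of the variance separated the numbers. The block called 22 of 22 choroid plexus genes and 16 of 18 meningeal genes, and all 367 genes of the covariate fit were among its 485. Lists past the threshold numbered 0 with an estimated correlation and 0 with fry, 13 to 19 under the other settings, 16 to 19 with a sample left out and 15 without the choroid plexus and meningeal lists. TPM, which only rescales, ended the calls of the hypothalamus, CA1, monoamine and GABAergic lists, as did leaving out haemoglobin genes and rescaling the rest, so no effect of haemoglobin genes is shown. Median of ratios and quantile scaling ended the last 3 of these, and the minimum of 5 FPKM the hypothalamus, monoamine and GABAergic lists. No filter ended the monoamine call, a pseudocount of 0.1 the hypothalamus call, and the block and covariate the GABAergic call, while the block added oligodendrocyte (lower, adjusted p = 1.70e-04), immediate early (higher, 0.00239) and neocortex (higher, 0.0376) genes; the cause was not tested. No scaling turned a list, and the median of all genes moved from -0.018 to 0.033 (TPM), 0.015 (median of ratios) and 0.030 (quantile). Pearson's r without a filter was 0.980 for PBS 1 and PBS 2, 0.962 for PBS 1 and ascorbate 2, 0.975 for PBS 2 and ascorbate 1 and 0.971 for the ascorbate samples. With a pseudocount of 0.1 it was 0.901 for PBS 1 and ascorbate 2 and 0.924 for the ascorbate samples. Of 89 named genes tested, 49 passed with the block, 42 with the covariate and 1 after quantile normalization, which also turned Mbp to 0.28. Directions turned with a sample left out, where log2 differences ran from -0.24 to 0.33 for Myh9, -0.74 to 3.87 for Prl, -0.80 to 4.35 for Hcrt, -3.07 to 4.51 for Pmch, -0.21 to 0.68 for Hap1, -0.71 to 3.07 for Th and -0.75 to 3.14 for Slc6a3. They ran from -0.0051 to 1.32 for Lefty1, -0.073 to 1.14 for Pou3f1, -3.04 to 1.16 for Ccdc153, -2.35 to 0.16 for Rsph1, -0.28 to 0.46 for Cplx1, -2.03 to 1.78 for Calb2 and -1.28 to 1.90 for Prkcd, and from -0.63 to 0.40 for Mbp and -1.30 to 0.50 for Trf. List means ran from -0.34 to 0.023 (ribosomal), -0.080 to 0.46 (synaptic), -1.81 to 0.23 (ependymal), -0.38 to 0.068 (oxidative phosphorylation), -0.49 to 0.065 (antioxidant), -0.998 to 2.44 (hypothalamus), -0.43 to 1.38 (CA1) and -0.42 to 1.11 (monoamine). The choroid plexus, meningeal, vascular, interferon and antigen presentation lists kept their direction and camera call with each sample left out. The count models could not be run, since the values are FPKM, and the unknown depth limits what can be said of genes near 0.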

Other observations

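The tests of both patterns weighed here were chosen after the results had been seen.

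Splitting the 4 samples by number instead of treatment gave more genes past the threshold than the treatment did, although the list with the largest shift, choroid plexus at -3.52, belonged to the treatment. In limma-trend fits of a single split, without a block, 1602 genes passed between the numbers after Benjamini-Hochberg adjustment, 929 lower and 673 higher in number 2. In such fits 0 genes passed between the treatments and 0 for the remaining split, which points to a structure of the samples. Markers of the thalamus and habenula, which lie beneath the hippocampus, fell in number 2 by a median log2 of -2.55, with 18 of 20 genes past the threshold (camera, adjusted p = 1.22e-16, adjusted p = 0.554 with an estimated correlation). Oligodendrocyte and myelin genes fell by -1.07 (20 of 23 genes past the threshold, camera adjusted p = 6.47e-12, adjusted p = 0.752 with an estimated correlation). Hypothalamus and pituitary genes fell by -2.26 (camera adjusted p = 1.50e-05, adjusted p = 0.752 with an estimated correlation). The ependymal, striatum, astrocyte, ribosomal, oxidative phosphorylation, antioxidant and heat shock lists fell as well, by medians of -1.20, -0.60, -0.43, -0.33, -0.37, -0.39 and -0.30 (camera, adjusted p from 1.03e-06 to 0.0302), with adjusted p from 0.752 to 0.892 with an estimated correlation. Markers of 2 hippocampal fields rose in number 2, CA1 markers by a median of 1.59 (camera adjusted p = 8.23e-08, adjusted p = 0.752 with an estimated correlation) and dentate gyrus markers by 0.65 (camera adjusted p = 3.60e-08, adjusted p = 0.745 with an estimated correlation), while CA2 and CA3 markers did not pass (median 0.15, camera adjusted p = 0.516). Glutamatergic synapse genes rose by 0.72 and immediate early genes by 0.51 (camera adjusted p = 9.92e-11 and 5.30e-06, adjusted p = 0.752 each with an estimated correlation).

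The choroid plexus markers were lower in both ascorbate samples. Scaling or depth is argued against, since the median of all tested genes was -0.018 (SD 0.33 over genes) while the list lay at -3.52. Different thalamus content is argued against as well, since between samples of 1 number, whose thalamus markers differed by 0.24 and -0.029, the choroid plexus medians were -3.19 and -3.83. The presence of choroid plexus tissue in the PBS samples with little of it in the ascorbate samples, and lower expression in choroid plexus cells that were still present, both stay open and cannot be told apart. That 22 of 22 markers were lower by 2 or more on the log2 scale restates the pattern and favours neither, and the smallest change, -2.57 in Prlr, leaves no marker at its former level to show that the cells were there, so an effect of ascorbate on this epithelium stays untested.

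Samples of the same number were closer to each other than samples of the same treatment. Scaling or depth is argued against, since the median difference of all tested genes between the numbers was -0.082 while the thalamus list lay at -2.55. Tissue from outside the hippocampus in the samples numbered 1 is a candidate explanation, and 20 of 20 thalamus and habenula markers were higher in both of these samples, among them the most abundant, Cplx1, Calb2 and Prkcd, although 15 of the 20 were at 1 FPKM or more in every sample and 3 belong to another list. The count of 20 of 20 goes with that explanation, but the test was chosen after the results had been seen. Other biological explanations were not tested, since the labels give the numbers no meaning.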
